A study of Mus musculus with 4 samples.

How the data were processed

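Messenger RNA of proliferating C2C12 myoblasts was measured in 4 strand-specific libraries, 2 with an empty retroviral vector and 2 with C/EBPβ overexpression, sequenced on an Illumina HiSeq 2500 per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The labels speak of pooled stable cells and do not say whether the replicates of a group came from separate transductions or cultures, so p-values measure only the spread between these samples, which may be technical.

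Per the file headers, the deposited counts are whole-number counts of fragments per gene made with featureCounts 1.5.1 in reverse-stranded paired-end mode on GENCODE M12, without counting multi-mapping or ambiguous reads. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.4 to GRCm38, counted with featureCounts 1.4.6 and compared with DESeq2, whose version is not given in the sources used here. The 2 statements of the featureCounts version differ, and which is right was not settled. Because multi-mapping reads were left out, genes with near-identical copies can be under-counted. The authors' deposited table of a comparison has the column names of DESeq2: a base mean (signal), a log2 fold change with its standard error on the log2 scale, a test statistic (score), and a p-value with its adjusted p-value. The statistic equals the log2 fold change divided by its standard error. The libraries behind the deposited base mean signal are not given in the sources used here. That table was described and not retested.

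Counts for 49585 genes were read as deposited. Symbols came from the reference annotation of the same genome build, which matched 49326 identifiers. Genes with too few counts were removed with filterByExpr of edgeR at its defaults (minimum count 10, minimum total 15), which left 15078 genes, and 22962 genes had 0 counts in all libraries. Library totals were 40912955 and 37566321 counts (empty vector) and 38656497 and 92027838 (C/EBPβ), so that 1 count equals 0.0244, 0.0266, 0.0259 and 0.0109 CPM. Mitochondrially encoded transcripts took 1.38% and 0.954% of empty vector counts and 1.31% and 1.13% of C/EBPβ counts, and the 20 most abundant genes between 6.27% and 7.25%. CPM per gene were computed here from the deposited counts of the tested genes with the TMM factors of edgeR, while the values of 1 count, the lower bounds, the ratios and the summed CPM of leukocyte genes used library totals.

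The groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with TMM scaling and no covariate, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with calls at 0.05. Fold changes are C/EBPβ over empty vector. A fold against a group with 0 counts is a lower bound computed against 3 counts over the group, and with 1 to 3 counts a ratio with a 95% counting interval is given instead. Such bounds and intervals cover counting error only. Medians of the lists that hold genes with 0 counts were the same with those genes at their bound.

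Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, beside camera with an estimated correlation and fry. With 4 libraries the estimated form has few residual degrees of freedom and little power. A list that it leaves uncalled is therefore not shown to be unchanged. Shares, medians and list tests cover tested members only, so members with too few counts in both groups are left out. With a library left out the filter was run again, which left 15587 to 15691 genes. A list's median can then cover other members than in the 4 libraries. Before the data were examined, 28 lists were fixed: C/EBP family, myogenic regulators, sarcomere and excitation-contraction, satellite cell and Notch, cell cycle G1 and S, cell cycle G2 and M, p53 targets and CDK inhibitors, acute phase and complement, cytokines and chemokines, interferon response, NF-κB targets, adipogenesis and lipid storage, cholesterol biosynthesis, collagens and matrix, matrix proteases and inhibitors, muscle atrophy and ubiquitin ligases, TGF-β and BMP response, integrated stress response, ER chaperones, antioxidant response, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded transcripts, cytosolic ribosomal proteins, and markers of macrophages and leukocytes, of endothelial and mural cells, of osteoblasts and chondrocytes, and of fibroblasts and fibro-adipogenic cells. Some genes stand in more than 1 list, such as Cebpa, Cxcl1 and Ccl2.

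The rule for named genes was fixed at the same time. It takes the C/EBP family, Myod1, Myf5, Myog, Pax7 and Mki67 whatever their result, and the 12 largest and 12 smallest log2 fold changes among called genes with a mean of at least 5 CPM and groups that do not overlap, leaving out predicted genes and pseudogenes. From each list it takes up to 2 called members in each direction with the smallest adjusted p, or, where no member passed, the 2 most abundant. Some genes that the rule takes are not reported here. Tyrobp, Ptprc and Myh3 in the results, and genes named first in the closing section, fall outside the rule and were chosen after their values were seen.

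Both replicate pairs differed by more than sampling noise (chi-square per degree of freedom 22.8 and 25.1), so none was counted as a duplicate. Across genes, log2 CPM correlated at 0.994 and 0.995 within groups and at 0.956 to 0.971 between them, and genes are not independent replicates.

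The edgeR steps were tested on simulated data for this comparison, over 14833 genes, with known changes in 67 genes at 1.5-fold, 67 at 2-fold and 66 at 4-fold. At 1.5-fold 55.2% of changed genes were recovered, at 2-fold 79.1% and at 4-fold 98.5%, and 13 of 168 calls were false. Far fewer genes were changed in the simulation than were called in the real data (24.9% of those tested). Recovery and false calls depend on that share, so these rates need not hold for the real comparison. Alternatives were other scalings, no filter and a stricter filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, the block with a GC and gene-length offset (GC was known for 99.8% of tested genes), each library left out in turn, a test against a 1.5-fold change, removal of the 20 most abundant genes or of Cebpb, other settings of the list test, and thinning of C/EBPβ replicate 2 to the total of replicate 1. Figures were drawn with matplotlib 3.10.9.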

Results

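C2C12 is a mouse myoblast line of C3H origin that grows as single cells in serum-rich medium and forms contractile myotubes when serum is withdrawn. Messenger RNA was measured by strand-specific sequencing in 4 libraries of proliferating C2C12 cells. In 2 libraries the cells carried an empty retroviral vector, and in 2 they carried a retrovirus for overexpression of C/EBPβ, a leucine-zipper transcription factor encoded by Cebpb. Transduced cells were selected as pools in 1200 μg/ml G418 for 7 days and then proliferated for 48 h, in medium whose stated serum content is 10% for the line. The libraries held 40912955 and 37566321 counts assigned to genes for the empty vector, and 38656497 and 92027838 for C/EBPβ. The comparison asks which transcripts differ between myoblasts with forced C/EBPβ and control myoblasts kept in growth conditions.

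C/EBPβ myoblasts had less RNA for muscle differentiation and more RNA for acute-phase proteins, collagens and other matrix proteins. Myog, the transcription factor that starts terminal muscle differentiation, fell from 56.2 ± 6.80 to 8.11 ± 3.94 CPM (counts scaled by the library's total over the tested genes and its TMM factor, mean ± SD, n = 2 per group). Genes of the sarcomere and of excitation-contraction coupling fell in 32 of 37 tested members, with a median log2 fold change of -1.76. Of 26 acute-phase and complement genes 16 had enough counts to be tested, and 12 of these rose, with a median log2 fold change of 2.58. Collagens and matrix genes rose in 26 of 33 tested members, with a median of 1.23. Cebpb itself rose from 80.9 ± 5.77 to 478 ± 7.00 CPM.

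Cebpb (ENSMUSG00000056501) lies on chromosome 2 from 167688915 to 167690418 on the plus strand of GRCm38 and is annotated as a protein-coding gene of 1 exon. Its log2 fold change was 2.56 (SE 0.09), with adjusted p = 3.03e-06 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, which is the test behind every adjusted p of a gene given here. Reads of the vector-borne copy, where they map to this gene, are added to those of the chromosomal copy in this value, and the copies were not told apart. Of the 6 tested members of the C/EBP family, 2 rose, both over all genes tested and adjusted over the list alone. The other riser was Cebpa, a partner of Cebpb in fat-cell differentiation, at 34.3 ± 9.63 against 18.5 ± 3.33 CPM (log2 fold change 0.89, adjusted p = 0.0119). Without empty vector replicate 2 the Cebpa call was lost (log2 fold change 0.71, adjusted p = 0.0803). Cebpd had a log2 fold change of 0.43 (adjusted p = 0.200), which passed without C/EBPβ replicate 2 (0.66, adjusted p = 0.0134) and with no low-count filter (0.44, adjusted p = 0.0389), and Cebpg had -0.13 (adjusted p = 0.286). Cebpz and Ddit3 had values of 0.02 and 0.01, whose signs turned when libraries were scaled by their totals only, and Cebpe had 0 counts in all 4 libraries. The list as a whole did not pass the camera test (adjusted p = 0.190).

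**Figure D1:**
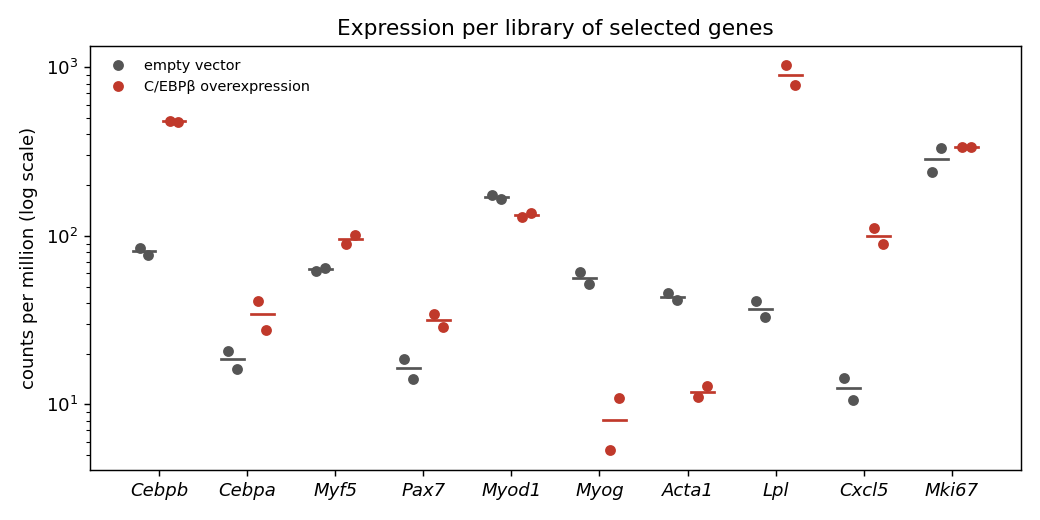
CPM on a log axis for 10 genes, with 1 point per library, grey for empty vector and red for C/EBPβ overexpression, and a line at each group's mean. Cebpb stood at 478 against 80.9 CPM and Myog at 8.11 against 56.2 CPM, while Mki67 stood at 336 against 284 CPM, with the 2 empty vector libraries spread by more than that difference.

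Across the transcriptome, 3759 of 15078 tested genes (24.9%) passed an adjusted p of 0.05, with 2129 higher and 1630 lower in C/EBPβ cells. At least 2-fold differences were seen in 1463 of them, 941 higher and 522 lower. Without C/EBPβ replicate 1 the count fell to 2493 genes, 1527 higher and 966 lower, and a test against a 1.5-fold change called 1259, 808 higher and 451 lower.

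Among the 12 largest rises, Cxcl14, a chemokine, had 0 counts in both empty vector libraries and 23.8 ± 5.57 CPM with C/EBPβ, which is at least 577-fold higher against a floor of 3 counts over the group. The bound was 276-fold without empty vector replicate 1 and 301-fold without empty vector replicate 2. Stc1, a secreted glycoprotein hormone, went from 0.613 ± 0.179 to 380 ± 10.5 CPM (log2 fold change 9.28, SE 0.16, adjusted p = 3.35e-08), and Sfrp1, a secreted Wnt antagonist, from 1.96 ± 0.187 to 346 ± 24.9 CPM (7.47, SE 0.13). Prg4, the joint lubricant lubricin, reached 298 ± 105 CPM from 1.75 ± 0.0760. Alpl, tissue-nonspecific alkaline phosphatase, reached 194 ± 126 CPM from 0.0994 ± 0.0658, a log2 fold change of 10.87 that was 9.99 without C/EBPβ replicate 1. Without empty vector replicate 1 the remaining control held 2 counts of Alpl, and the ratio was 2947 (95% counting interval 816 to 24338). Lama1, a laminin chain, had a log2 fold change of 9.36, which was 8.44 without empty vector replicate 2. Without empty vector replicate 1 the remaining control held 0 counts of Lama1, and its level with C/EBPβ was at least 529-fold higher against 3 counts. Angptl7 and Orm1 had 2 and 3 counts over both empty vector libraries, so their rises are given as ratios with 95% counting intervals, 617 (171 to 5101) and 515 (176 to 2500). For Angptl7 the ratio was 296 (81.7 to 2442) without empty vector replicate 1. Without empty vector replicate 2 the remaining control held 0 counts of Angptl7, and its level was at least 215-fold higher against 3 counts. The remaining genes of the upper 12 were Gda, Angpt4, Ptx3 and Adam23, with log2 fold changes of 7.19, 6.41, 6.30 and 5.69.

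Among the 12 largest falls, Nptx1, a neuronal pentraxin, fell from 91.5 ± 21.7 to 3.67 ± 3.22 CPM (log2 fold change -4.49, SE 0.45, adjusted p = 2.72e-04), and the neurofilament genes Nefl and Nefm fell by 4.14 and 2.67 on the log2 scale. Ngfr, a neurotrophin receptor, fell by 4.46, Dkk2, a secreted Wnt antagonist, by 3.95, and Erbb3, a neuregulin receptor, by 3.05. The other genes of the lower 12, beside Myog, were Adgrl3, Podxl, Edil3, Ppm1e and Synpo2l, with log2 fold changes of -3.07, -2.93, -2.80, -2.75 and -2.62. Without C/EBPβ replicate 2 the log2 fold changes were -6.04 for Nptx1, -5.96 for Ngfr, -5.24 for Nefl and -3.85 for Erbb3. Each of these genes was higher in C/EBPβ replicate 2 than in replicate 1, so the falls were smaller in replicate 2. Levels in replicates 1 and 2 were 1.39 and 5.94 CPM for Nptx1 and 0.183 and 0.718 for Ngfr. They were 4.72 and 14.4 for Nefl and 1.31 and 2.96 for Erbb3, while Cebpb stood at 483 and 473 CPM.

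**Figure D2:**
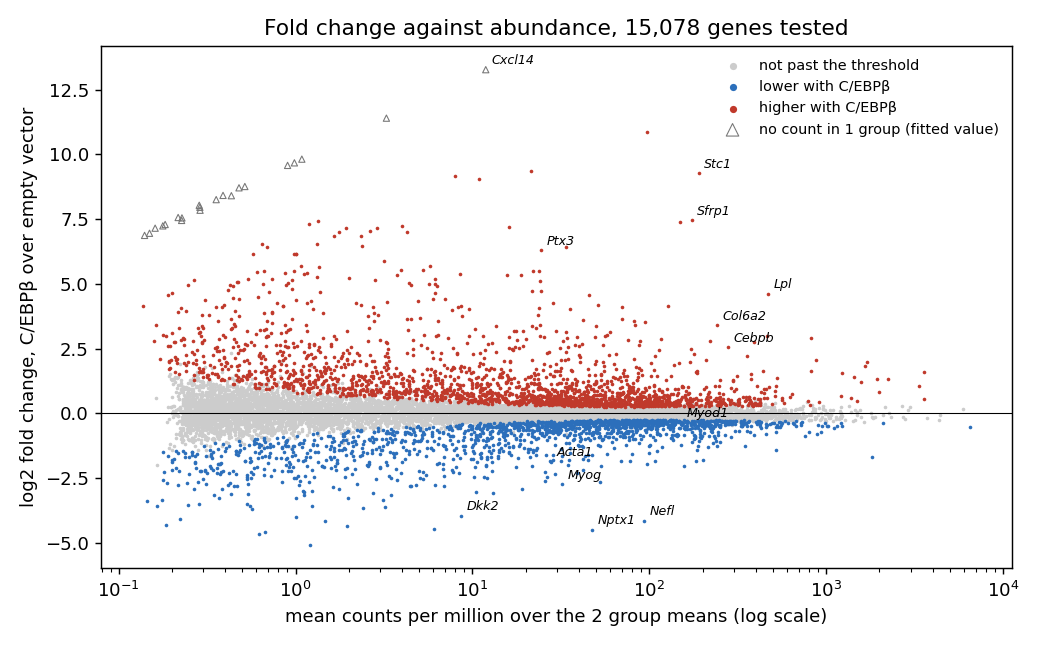
Log2 fold change of C/EBPβ over empty vector against mean CPM (log axis) for 15078 tested genes, red and blue for the 2129 higher and 1630 lower genes and grey for genes not past the threshold. Open triangles are genes with no count in 1 group, whose plotted value depends on the prior count and is no estimate of the fold; Stc1 and Sfrp1 stand at 9.28 and 7.47, Nptx1 at -4.49.

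Muscle genes moved mostly downward. Of 19 tested myogenic regulators, 10 fell and 2 rose (12 and 2 adjusted over the list alone; median -0.36, camera adjusted p = 0.00236, and adjusted p = 0.440 with an estimated correlation). Myog fell by 2.75 on the log2 scale (SE 0.27, adjusted p = 2.39e-04, and -3.40 without C/EBPβ replicate 2). It stood at 5.32 CPM in C/EBPβ replicate 1 and 10.9 CPM in replicate 2, so the fall was smaller in replicate 2. Mef2c, a partner of Myog in muscle transcription, fell by 2.30. Myod1, the determination factor, fell by 0.36, from 171 ± 6.72 to 133 ± 5.66 CPM (adjusted p = 0.0151), but not past the threshold without C/EBPβ replicate 1 (adjusted p = 0.152). Myf5, an earlier determination factor, rose from 63.1 ± 2.01 to 95.7 ± 8.04 CPM (0.60, adjusted p = 0.00179), as did Mustn1 (0.81). In the sarcomere and excitation-contraction list 32 of 37 fell and 1 rose (33 and 1 adjusted over the list alone, camera adjusted p = 9.33e-15, and adjusted p = 0.440 with an estimated correlation), among them Acta1, skeletal actin (-1.87), and Tnni1, slow troponin I (-2.32). The riser was Ldb3, a Z-disc protein (0.75, adjusted p = 0.0169), whose call was lost without empty vector replicate 1 (adjusted p = 0.107) and without empty vector replicate 2 (adjusted p = 0.0528). In the satellite cell and Notch list 10 of 20 fell and 3 rose (11 and 3 adjusted over the list alone; median -0.60, camera adjusted p = 0.00879, and adjusted p = 0.440 with an estimated correlation). Pax7, the satellite-cell factor, rose from 16.3 ± 3.08 to 31.5 ± 4.04 CPM (0.94, adjusted p = 0.00248), with the Notch ligand Jag1 (1.34) and the syndecan Sdc3 (1.64). The Notch ligand Dll1 fell by 1.58 and Tenm4 by 3.60, the latter from 2.32 to 0.174 CPM.

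In each of the 5 inflammatory and immune lists more members rose than fell. In the acute-phase and complement list 16 of 26 members could be tested, of which 12 rose and 4 did not pass (13 rose adjusted over the list alone). The median over tested members was 2.58 (camera adjusted p = 2.65e-08, and adjusted p = 0.440 with an estimated correlation). Among the risers was Ptx3, a pentraxin, from 0.600 ± 0.251 to 48.1 ± 14.2 CPM (6.30). Of 38 cytokines and chemokines 22 could be tested, of which 12 rose and 3 fell (13 and 3 adjusted over the list alone). Their median was 0.65, or 1.04 without empty vector replicate 1, over the members that then passed the filter. In the 4 libraries camera gave adjusted p = 0.00409, and adjusted p = 0.440 with an estimated correlation. Cxcl5, a neutrophil chemokine, rose from 12.4 ± 2.52 to 99.9 ± 15.2 CPM, while Tslp fell by 2.43 (-3.08 without C/EBPβ replicate 2) and Il34 by 1.29. Tslp stood at 0.682 CPM in C/EBPβ replicate 1 and 1.33 CPM in replicate 2. In the interferon response list 11 of 32 rose and 2 fell (13 and 2 adjusted over the list alone; median 0.30, camera adjusted p = 0.00407, and adjusted p = 0.440 with an estimated correlation). The MHC class I genes H2-K1 and H2-D1 rose by 2.78 and 1.96, whereas Ifit2 fell by 0.49 and Rsad2, both induced by interferon, by 2.35. Without C/EBPβ replicate 2 the remaining C/EBPβ library held 1 count of Rsad2 (ratio 0.0597, 95% counting interval 0.00147 to 0.356). Its call was lost without empty vector replicate 2 (-2.03, adjusted p = 0.110) and in DESeq2 (adjusted p = 0.0578). The interferon list's call was lost without empty vector replicate 1 (median 0.13, adjusted p = 0.190) and without C/EBPβ replicate 2 (median 0.13, adjusted p = 0.0882). Of 16 NF-κB targets 7 rose and 3 fell, with the same counts adjusted over the list alone (median 0.25, camera adjusted p = 0.0810). The list passed with limma-voom (adjusted p = 0.0488) and with the stricter filter of 5 CPM in 2 libraries (adjusted p = 0.0364), but not with an estimated correlation (adjusted p = 0.440 with an estimated correlation). Cxcl1 and Ccl2, both chemokines, rose by 2.99 and 1.12, and Tnfaip3 and Traf1 fell by 0.91 and 2.16 (Traf1 -3.45 without C/EBPβ replicate 2). Traf1 stood at 0.288 CPM in C/EBPβ replicate 1 and 0.98 CPM in replicate 2. Among 24 macrophage and leukocyte markers 6 could be tested, of which 3 rose, also adjusted over the list alone (median 0.53, camera adjusted p = 0.0470, and adjusted p = 0.440 with an estimated correlation). The call was lost without C/EBPβ replicate 2 (adjusted p = 0.141) and with a prior count of 0.5 (adjusted p = 0.0507), and the stricter filter left too few members to test. The median was 1.16 without empty vector replicate 1 and 0.97 without C/EBPβ replicate 1. Both cover the members that passed the filter in the remaining libraries, which may differ from the 6 tested in all 4. Lyz2, lysozyme, went from 0.0994 ± 0.0658 to 6.19 ± 1.85 CPM (5.88), with a ratio of 105 (95% counting interval 29.1 to 873) without empty vector replicate 1, where 2 control counts were left. Cd14 rose by 0.72, while Tyrobp had 0 counts in every library and Ptprc at most 2. H2 and Orm genes have close copies, and reads that map to several copies were not counted, so their levels are uncertain.

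In the collagens and matrix list 26 of 33 rose and 2 fell, with the same counts adjusted over the list alone (median 1.23, camera adjusted p = 2.65e-08, and adjusted p = 0.440 with an estimated correlation). Col6a2, a collagen VI chain, rose from 41.5 ± 5.71 to 440 ± 118 CPM (3.40), and Lama4, a laminin chain, by 5.17 (5.93 without empty vector replicate 2), while Col18a1 fell by 1.21 and Nid1 by 0.81. Of 26 matrix proteases and inhibitors, 15 rose and 3 fell (16 and 3 adjusted over the list alone; median 0.64, camera adjusted p = 0.00158, and adjusted p = 0.440 with an estimated correlation). Mmp19 and Adam12 rose by 2.94 and 2.62, and Mmp10 and Adam8 fell by 2.77 (-3.52 without C/EBPβ replicate 2) and 1.05. Mmp10 stood at 0.157 CPM in C/EBPβ replicate 1 and 0.327 CPM in replicate 2. In the TGF-β and BMP response list 17 of 21 rose and 1 fell, with the same counts adjusted over the list alone (median 1.16, camera adjusted p = 9.99e-06, and adjusted p = 0.440 with an estimated correlation). Its leading members were Tgfbi, a secreted matrix protein (5.05), and Cnn1, a smooth-muscle calponin (4.71; 5.33 without empty vector replicate 1). The single fall was that of Nog, a BMP antagonist (-0.74, adjusted p = 0.0182), lost without empty vector replicate 1, without empty vector replicate 2 or without C/EBPβ replicate 2 (adjusted p = 0.0802, 0.0532 and 0.0872).

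Markers of other mesenchymal and vascular cells moved both ways. Of 8 tested endothelial and mural markers 5 rose and 1 fell (6 and 1 adjusted over the list alone; median 1.01, camera adjusted p = 0.0456, and adjusted p = 0.566 with an estimated correlation). The call was lost without empty vector replicate 2 (adjusted p = 0.0538), with a prior count of 0.5 (0.0507) and with the stricter filter (0.115), and the median was 0.62 without C/EBPβ replicate 1. Pdgfrb, a receptor of mural cells and fibroblasts, rose from 174 ± 22.5 to 424 ± 66.8 CPM (1.28), and Kcnj8 from 0.0618 ± 0.0501 to 0.523 ± 0.0013 CPM (log2 fold change 2.40 without empty vector replicate 2). Without empty vector replicate 1, where 1 control count of Kcnj8 was left, the ratio was 19.5 (95% counting interval 3.39 to 783). Flt1, a VEGF receptor, fell by 0.53 (adjusted p = 0.0533 without empty vector replicate 1 and 0.0550 without C/EBPβ replicate 2). Among 12 fibroblast and fibro-adipogenic markers 5 rose and 2 fell, with the same counts adjusted over the list alone (median 0.13, camera adjusted p = 0.239). Pdgfra rose by 2.57 and Mfap5 by 3.74 (4.33 without empty vector replicate 1), while Cd34 fell by 0.70 (adjusted p = 0.0751 without empty vector replicate 1) and Vim, vimentin, by 0.55 (adjusted p = 0.0647 without it). The osteoblast and chondrocyte list split evenly, 4 of 12 rising and 4 falling, likewise adjusted over the list alone (median 0.28, and -0.11 without C/EBPβ replicate 1; camera adjusted p = 0.734, with the test's direction turned in limma-voom). Beside Alpl, Col10a1 rose by 3.39 (2.67 without C/EBPβ replicate 1), and Sox9 and Dlx3, transcription factors of skeletal development, fell by 1.04 and 0.94.

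The adipogenesis, glycolysis and atrophy lists held members that rose and members that fell. In the adipogenesis and lipid storage list 8 of 22 rose and 4 fell (9 and 4 adjusted over the list alone; median 0.12, camera adjusted p = 0.115). Lpl, lipoprotein lipase, rose from 36.9 ± 5.79 to 906 ± 175 CPM (4.62). Fabp4, a fatty acid carrier of fat cells, rose from 0.174 ± 0.0971 to 7.35 ± 2.88 CPM (5.34, and 6.06 without empty vector replicate 1). Cd36 fell by 2.34 from a low level (0.972 to 0.182 CPM) and Klf5 by 1.02. Of 22 cholesterol synthesis genes 3 fell, also adjusted over the list alone (median -0.04, camera adjusted p = 0.148). Insig1, a regulator of sterol synthesis, fell by 0.40, and its call was lost without C/EBPβ replicate 1 (adjusted p = 0.215) and without empty vector replicate 2 (adjusted p = 0.0604). In the glycolysis and hypoxia list 7 of 24 rose and 3 fell, with the same counts adjusted over the list alone (median 0.01, camera adjusted p = 0.246). Pdk1, which restrains pyruvate oxidation, rose by 0.90 and Vegfa by 0.77. Egln3 fell by 0.61 (adjusted p = 0.0898 without empty vector replicate 1) and Pfkp by 0.34 (adjusted p = 0.0759 without empty vector replicate 2 and 0.214 without C/EBPβ replicate 1). Of 24 muscle atrophy genes 9 rose and 3 fell (10 and 4 adjusted over the list alone; median 0.14, camera adjusted p = 0.243, 0.0253 with the stricter filter, and adjusted p = 0.440 with an estimated correlation). Inhbb, an activin subunit, rose from 13.9 ± 0.426 to 66.5 ± 1.74 CPM (2.26) and Fst, an antagonist of activin, by 2.86. The muscle ubiquitin ligase genes Trim63 and Fbxo40 fell by 2.35 and 1.64, both from low levels. Trim63 went from 0.631 to 0.118 CPM (50 and 16 counts per group) and Fbxo40 from 1.02 to 0.328 CPM. The Fbxo40 call was lost without empty vector replicate 2 (log2 fold change -1.34).

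Mki67, a proliferation marker, was at 284 ± 65.5 CPM with empty vector and 336 ± 0.0991 CPM with C/EBPβ (log2 fold change 0.24, adjusted p = 0.262), but passed without empty vector replicate 2 (0.49, adjusted p = 0.0138). In the G1 and S list 7 of 31 fell and 24 did not pass, also adjusted over the list alone (median -0.16, camera adjusted p = 0.00154; adjusted p = 0.440 with an estimated correlation). Ccnd1, cyclin D1, fell from 465 ± 35.3 to 282 ± 19.2 CPM (-0.72), and Ccne2 by 0.34 (adjusted p = 0.0555 without empty vector replicate 1 and 0.202 without C/EBPβ replicate 1). In the G2 and M list 4 of 32 fell (2 adjusted over the list alone; median -0.10, camera adjusted p = 0.0249; adjusted p = 0.643 with an estimated correlation). That call was lost without empty vector replicate 2 (median -0.09, adjusted p = 0.132) or C/EBPβ replicate 1 (median -0.04, adjusted p = 0.182), and the median was -0.16 without C/EBPβ replicate 2. Ect2 and Cdc25b fell by 0.45 and 0.40, and neither passed without C/EBPβ replicate 1 (adjusted p = 0.0900 and 0.112). Of 22 p53 targets and CDK inhibitors 8 fell and 3 rose (9 and 5 adjusted over the list alone; median -0.20, camera adjusted p = 0.0456; adjusted p = 0.440 with an estimated correlation). Its call was lost without empty vector replicate 1 (median -0.12, adjusted p = 0.128), empty vector replicate 2 (0.0607) or C/EBPβ replicate 2 (0.0833). Pmaip1, a pro-apoptotic gene, fell by 1.80 and Plk2 by 0.89, while the death receptor gene Fas rose by 1.30 and Trp53inp1 by 0.49.

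In the integrated stress response list 13 of 26 fell and 2 rose (14 and 3 adjusted over the list alone; median -0.36, camera adjusted p = 0.00154, and adjusted p = 0.440 with an estimated correlation). Atf3, a stress transcription factor, fell from 16.6 ± 0.173 to 5.57 ± 0.691 CPM (-1.56) and Phgdh, of serine synthesis, by 0.84, while Vldlr and Ddit4 rose by 1.58 and 0.78. Of 19 chaperone genes 7 rose and 12 did not pass (9 rose adjusted over the list alone; median 0.22, camera adjusted p = 0.00154, and adjusted p = 0.440 with an estimated correlation), with Calr, calreticulin, at 2540 ± 58.7 against 1454 ± 97.2 CPM (0.80) and Herpud1 higher by 0.62. In the antioxidant list 6 of 21 fell and 2 rose (7 and 2 adjusted over the list alone; median -0.12, camera adjusted p = 0.0603). The list passed without empty vector replicate 2 (median -0.27, adjusted p = 0.0236) and with limma-voom (adjusted p = 0.0346), and had adjusted p = 0.440 with an estimated correlation in the 4 libraries. Gsta4 and Nqo1 fell by 1.04 and 0.81, and Hmox1 and Tkt rose by 0.44 and 0.35, the last not past the threshold without C/EBPβ replicate 1 (adjusted p = 0.137). Oxidative phosphorylation genes fell in 8 of 32 members (9 adjusted over the list alone). Their median was -0.19 (camera adjusted p = 6.38e-04, and adjusted p = 0.566 with an estimated correlation). Among them were Ppargc1a, a regulator of mitochondrial biogenesis, at a low level (-2.20, from 1.25 to 0.257 CPM), and Uqcrfs1 (-0.49). The Uqcrfs1 call was lost without C/EBPβ replicate 1 (log2 fold change -0.39). By edgeR 0 of 12 mitochondrially encoded transcripts and 0 of 37 cytosolic ribosomal protein genes passed, also adjusted over the list alone, with 0 and 1 at an unadjusted p under 0.05 and 0 in each by DESeq2 and by limma-voom. Their medians were 0.04 and -0.08 (camera adjusted p = 0.734 and 0.0725). The mitochondrial list's direction turned without empty vector replicate 2 (median -0.31) and without C/EBPβ replicate 1 (-0.15), and it passed without empty vector replicate 1 (0.53, adjusted p = 0.0166), with adjusted p = 0.922 with an estimated correlation in the 4 libraries. The ribosomal list passed without empty vector replicate 2 (-0.18, adjusted p = 2.72e-05) and turned without empty vector replicate 1 (0.05), and had adjusted p = 0.783 with an estimated correlation in the 4 libraries. Values for mt-Co1 and Rpl8 were 0.23 and -0.18, for mt-Cytb 0.14 (-0.11 without empty vector replicate 2), and for Rpl4 0.00 (-0.02 with libraries scaled by their totals only).

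**Figure D3:**
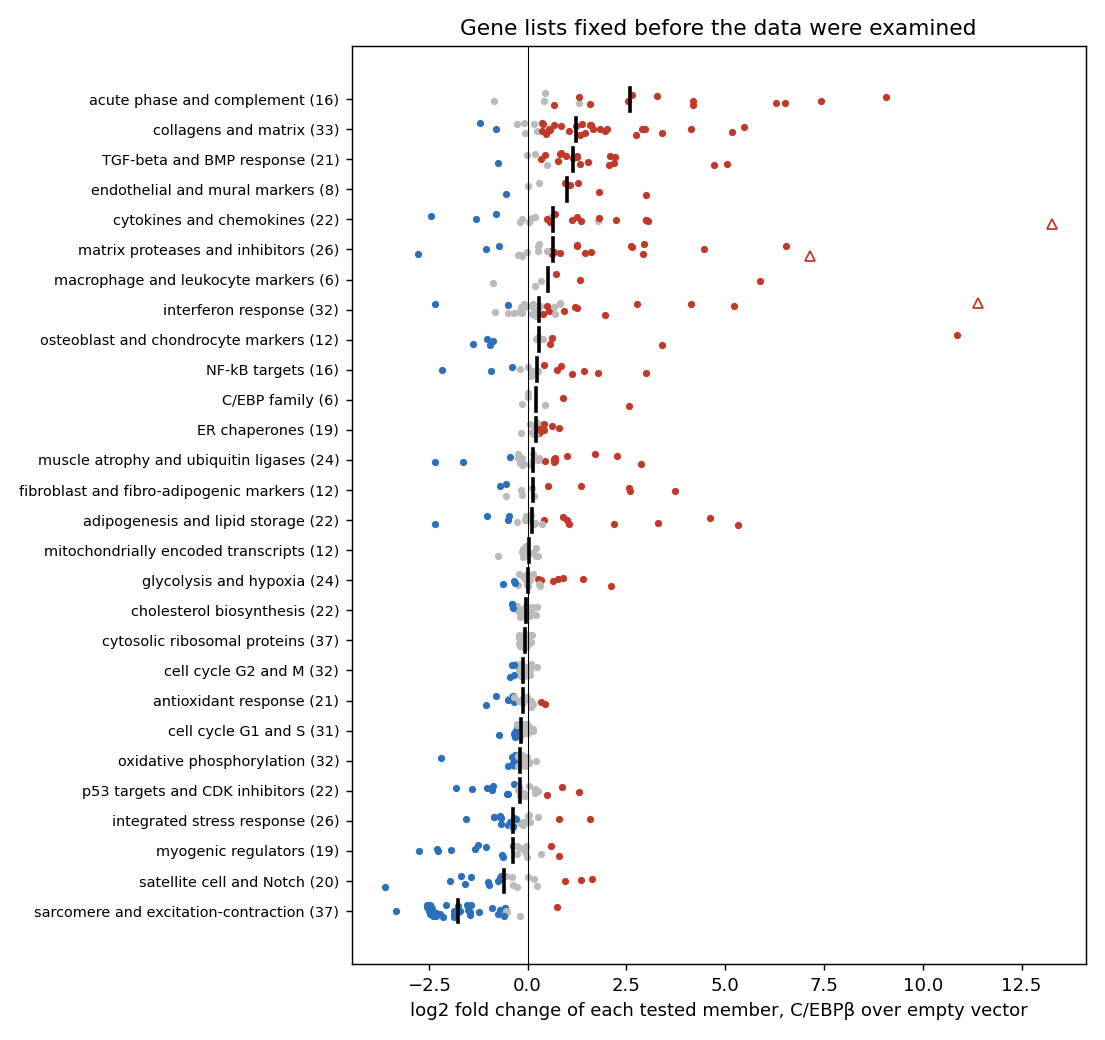
Log2 fold change of each tested member of 28 gene lists, C/EBPβ over empty vector, with the number tested in parentheses, red for higher, blue for lower, grey for not past the threshold, and a black bar at the list median. Open triangles are members with no count in the empty vector libraries, at a fitted value that is no estimate of the fold; medians run from -1.76 for sarcomere genes to 2.58 for acute-phase and complement genes.

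Over the 28 lists, camera with a preset correlation of 0.01 called 17, 9 upward and 8 downward. With an estimated correlation it called 0, and 0 had an unadjusted p under 0.05. Calls were lost also where the estimated correlation lay below the preset, as for ER chaperones (-0.0283, camera p = 4.40e-04 preset and 0.0622 estimated). It was high for oxidative phosphorylation (0.674) and mitochondrially encoded transcripts (0.975). With few residual degrees of freedom in 4 libraries the estimated form has little power, so its missing calls do not decide against a list. The fry test, whose directional p asks whether a list's genes move on balance one way and whose mixed p asks whether they change in either direction, called 18 lists directionally, 12 of them shared with camera, and 25 by the mixed p. The lists called by camera and not by directional fry were myogenic regulators, G2 and M, TGF-β and BMP response, oxidative phosphorylation, and endothelial and mural markers. Those called by directional fry and not by camera were the C/EBP family, NF-κB targets, adipogenesis and lipid storage, muscle atrophy, glycolysis and hypoxia, and fibroblast and fibro-adipogenic markers. Neither fry p compares a list with other genes.

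The authors' deposited table of the same contrast lists 18378 genes, of which 4313 pass an adjusted p of 0.05, 2051 higher and 2262 lower. For Cebpb the authors' deposited table gives a log2 fold change of 2.51 (SE 0.0874, adjusted p = 3.13e-178), and 2.56 was found here with edgeR. Of the 3759 genes called here, 3509 pass in the authors' deposited table, and all 3509 have the same sign there. A further 744 genes pass in the authors' deposited table and were tested but not called here. Base means in the authors' deposited table lie within 1% of the mean normalised count of these 4 libraries for 3.03% of genes. Myh3, embryonic myosin heavy chain, has a base mean of 104949 in the authors' deposited table and a mean normalised count of 558 in these libraries.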

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

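All alternatives were planned except the thinning of C/EBPβ replicate 2, which was chosen after seeing the data. The number of called genes lay between 3477 and 4536 with other scalings, DESeq2, limma-voom, no filter, the replicate block, and without the 20 most abundant genes or Cebpb, against 3759. It was 2724 with the stricter filter, where fewer genes were tested, and 3658 after thinning. Genes called in both settings had the same sign in every alternative run. Leaving out 1 library gave 2493 to 3462 called, 1527 to 2076 higher and 966 to 1386 lower genes, with 1 sample left in a group and assumed to vary like the other group. A test against a 1.5-fold change gave 1259 genes, 808 higher and 451 lower, since it asks for more. The labels do not pair the libraries, and deviations of same-numbered libraries correlated at 0.147 over 2 pairs. The replicate block called 4536 genes, 2573 higher and 1963 lower, 3756 of them among the 3759, and with a GC and length offset 5626, 2629 of them lower. Cebpd passed with the block (0.46, adjusted p = 0.0208, edgeR) and with block and offset (adjusted p = 0.0132), as did Mki67 (0.24, adjusted p = 0.0272) and mt-Co1 (0.26, adjusted p = 0.0399) with block and offset only. The block ended the list calls of p53 targets and of macrophage markers, a prior count of 0.5 ended those of macrophage and of endothelial markers, and the stricter filter ended that of endothelial markers and left too few macrophage markers to test. The stricter filter added NF-κB targets (adjusted p = 0.0364) and muscle atrophy (0.0253), and limma-voom, with 19 lists called, NF-κB targets (0.0488) and the antioxidant list (0.0346), each at adjusted p = 0.440 with an estimated correlation. Cebpb kept its direction and call in every alternative in which it was tested.

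Of 115 named and tested genes 90 kept direction and side of the threshold in every setting run, and 18 of 106 called ones lost the call in at least 1. Directions turned for 4 genes, all uncalled, and the cause was not tested. With totals only, values were -0.0032 for Cebpz, -0.0066 for Ddit3 and -0.018 for Rpl4. Upper-quartile factors gave -0.0037 for Ddit3 and -0.015 for Rpl4, DESeq2 -0.0050 and the block with offset -0.0026 for Rpl4, and thinning -0.0037 for Cebpz. With 1 library left out, values ran from -0.013 to 0.042 for Cebpz, -0.055 to 0.078 for Ddit3, -0.070 to 0.070 for Rpl4 and -0.11 to 0.44 for mt-Cytb, and list medians from -0.11 to 0.40 for osteoblast and chondrocyte markers, -0.18 to 0.048 for ribosomal proteins and -0.31 to 0.53 for mitochondrially encoded transcripts. The osteoblast and chondrocyte list's test turned direction with limma-voom (median 0.18). The number of lists called was 0 with an estimated correlation, against 17, and 14 to 16 with 1 library left out. Depth limits low genes, as 1 count is 0.0266 CPM in the shallowest library.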

Other observations

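Genes in this part that the results do not name were chosen after the values had been seen, as were the tests of explanations, except that the fits without C/EBPβ replicate 2 were planned. The tests of the deeper library, of interferon and of differentiating cells replaced first forms already run. For the deeper library the first form used the thinned library, which could hardly move a median. For differentiating cells it used 131 genes with a deposited base mean at least 10 times the mean here, of which 87.8% had a negative log2 fold change. Of genes of antigen presentation by MHC class I, 14 were picked because of their values, which is no test of the group, and all 14 were higher in C/EBPβ cells by the edgeR quasi-likelihood test, among them Nlrc5, the transcriptional activator of the class I genes, from 4.20 ± 1.09 to 41.6 ± 7.49 CPM (n = 2 per group; log2 fold change 3.31, adjusted p = 1.86e-05). The peptide transporter genes Tap1 and Tap2 rose by 4.13 and 2.56, H2-Q4 by 2.66, and the light chain gene B2m went from 315 ± 41.6 to 631 ± 45.9 CPM. Psmb8, an immunoproteasome subunit, had 0 counts in both empty vector libraries and 6.53 ± 1.52 CPM with C/EBPβ, at least 158-fold higher against 3 counts over the group. The H2 genes have close copies, so that the levels of single members are uncertain.

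Further genes picked by their values belong to no fixed list and test no theme. The Wnt antagonists Nkd2 and Notum rose by 4.58 and 2.52 on the log2 scale, beside Sfrp1 at 7.47, while Dkk2 fell by 3.95. Lef1, a transcription factor of the Wnt pathway, fell by 1.55, and Axin2, a Wnt target, was at -0.44 (adjusted p = 0.186, edgeR). The growth factor gene Hgf rose from 28.2 ± 1.15 to 205 ± 17.2 CPM (2.86), and Fgf7 rose by 3.14, Fgf10 by 2.96 and Vegfd by 2.05. Il1rn, an antagonist of interleukin-1, rose by 3.42 and Slpi, a protease inhibitor, by 5.11. Stmn2, a neuronal microtubule regulator, fell from 252 ± 3.16 to 61.1 ± 8.43 CPM (-2.04), and Gap43, L1cam, Tubb3 and Uchl1 fell by 2.08, 1.86, 0.90 and 1.13, whereas Ncam1 rose by 0.51. Hmga2, a chromatin protein, fell by 1.43, Igf2bp2 by 1.11, Ccnd2 by 1.80 and Cdk6 by 1.27.

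Many acute-phase, complement and chemokine genes and the 14 MHC class I pathway genes were higher in C/EBPβ cells. Leukocytes in those cultures would bring their abundant transcripts, but the summed CPM of 10 leukocyte genes rose by 0.00887% of the summed rise of the called genes, Tyrobp had 0 counts in every library, and only Lyz2, Cd14 and Csf1r rose among the tested markers. Without the deeper library, C/EBPβ replicate 2, the acute-phase median was 2.99 over the members that then passed the filter, which argues against that library as the source. A response of interferon genes as a whole was tested in 2 forms: an earlier form, without 5 antigen presentation genes, left out called members and was set aside, with a median of 0.19 over 27 members (camera adjusted p = 0.152), and over all 32 members the median was 0.30 with quartiles of -0.10 and 0.85. The upper quartile lies under 1, a bound set after the median was known, so most members did not rise by 1 or more on the log2 scale. The MHC genes give no measure for comparison, as they were picked by their values and differ widely (0.43 for Tapbp, 4.13 for Tap1). A partial interferon response stays open, since Irf1, Ddx58, Dhx58, Parp14 and Parp9 also rose. A difference between transduced pools, which the labels do not describe, stays open too. A C/EBPβ effect on these genes is a hypothesis.

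Sarcomere genes and Myog were lower in C/EBPβ cells. Without the deeper library, C/EBPβ replicate 2, the sarcomere median was -2.03, which argues against that library as the source. Fewer spontaneously differentiating cells in the C/EBPβ cultures may account for part or all of it. The 37 sarcomere members and Myog did not share 1 common fold change (chi-square per degree of freedom 20.4, quartiles of -2.37 and -0.78). Undifferentiated cells may also make part of this RNA, which allows unequal falls, so this spread does not decide the question. Since each library mixes all cells of a culture, a smaller share of differentiating cells cannot be told apart from lower expression per cell.

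Base means in the authors' deposited table lay above the mean of these 4 libraries for muscle genes. The median ratio over sarcomere genes was 49.1, against 0.941 over all listed genes with a middle 90% from 0.622 to 2.99, and 64 listed genes had 0 counts in all 4 libraries. A ratio of this size over sarcomere genes, far outside the middle 90%, argues against another count of the same 4 libraries as the whole cause. A candidate explanation is that the authors' fit included other libraries, which were not analysed here; the design of that fit is not given in the sources used here.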
